A study of Homo sapiens with 2 samples.

How the data were processed

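RNA-seq was measured in 2 libraries labelled MCF-7, 1 from a clone edited at FASN and 1 control, grouped by the genotype given in the labels. Per the labels' protocols, cells grew in a serum-supplemented medium, CRISPR/Cas9 was delivered on the PX459 plasmid, total RNA was taken with a column kit and libraries were made with a TruSeq RNA kit. Trimmomatic and STAR were used with build hg38, per the submitters' processing notes, which give no versions. The counting tool, the gene annotation, the strand setting, and whether the libraries come from separate cultures are not given in the sources used here.

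The deposited signal values are, from the values themselves, gene counts that the authors multiplied by 1 factor per library so that both columns sum to the same total, which equals the mean of both library totals (734036). Every low value was a whole multiple of 1 step per library (100% in both, tolerance 0.1 read). The step was 0.647 scaled units in the control and 2.21 in the edited library. Division by the step gave back whole reads, 1135391 in the control and 332680 in the edited library. The 10 genes with the most reads held 5.01% of reads in the control and 3.75% in the edited library. The authors' deposited table also holds their mean, ratio and log2 ratio per gene and a mark for selected genes. These were used only where the text names that table. The 58 marked genes were exactly those with a mean of at least 50 and an absolute log2 ratio of at least 2. Entrez identifiers were matched to RefSeq symbols for 27745 genes, and 650 had no match. Positions, GC content and transcript length came from GENCODE release 44 on hg38.

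The planned analysis had no test between conditions, since 1 library per group allows none. It consisted of the log2 ratio of the edited library over the control with a pseudocount of 1, counts of genes at least 2-fold apart, and the median ratio of gene lists. Each of 36 lists with at least 5 genes in the table was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart when its median lay outside the central 95% of these random lists. Of the 36 lists, 8 stood apart, 3 higher and 5 lower, where chance alone gives 1.8. The percentile describes these libraries and is not a p-value.

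Because whole reads could be recovered, an exact binomial test was added after the data were examined. It compares each gene's reads in both libraries given their totals, is two-sided by doubling the smaller tail, and was adjusted with the Benjamini-Hochberg method over 14328 genes at 0.05, and again over each list alone. Ratios have exact conditional Clopper-Pearson 95% intervals. A gene with no read in 1 library is given a bound against a floor of 3 reads per library. The floor is 1.94 scaled units in the control and 6.62 in the edited library. The bound takes the reads of the other library as exact, so the exact interval can allow a smaller fold. No fold is given when both libraries are at or under the floor. Reads carry no molecular identifiers, so intervals, floors and tests cover counting error only, and their p-values measure the difference between these 2 libraries.

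Genes were named by a rule fixed before the data were examined. FASN came first. The 12 highest and 12 lowest log2 ratios followed, among genes with a mean at or above the median of all genes. From each list came up to 4 members with the largest absolute log2 ratio. Since that rule often took members with few reads, members with at least 50 reads were added after the values were seen. Any further gene named, such as P4HB, ELOVL5 or TKT, was also chosen after its values were seen. The lists were fixed before the data were examined, apart from 3 in the closing section.

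All steps were tested on simulated reads for the real genes at the real depths, for the comparison of the edited clone with the control. With 200 genes changed among 28395, the binomial test called 48 of 50 genes raised 4-fold, 20 of 50 raised 2-fold, 10 of 50 lowered to 0.5 and 16 of 50 lowered to 0.25, with 2 of 28195 unchanged genes called. With no gene changed, 1 of 36 lists lay outside the central 95%, and a list of 25 genes raised 2-fold lay at percentile 100. In 20 simulated pairs without any change the test called 0 genes. The simulated reads vary by counting error only.

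Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, 3 other scalings (median ratio set to 0, equal upper quartiles, and a TMM factor trimmed by 30% on ratios and 5% on levels), a filter at the 25th percentile of the mean, thresholds of 1.5-fold and 4-fold, matching in 5 bins, and lists without shared members. Alternatives added later were a mean of at least 50, the binomial test, genes with at least 20 reads, removal of smooth trends on GC content and transcript length, the control thinned to the depth of the edited library in 100 draws, and genes without reads at their bound. Genes on the Y chromosome and XIST were left out of the tables of genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.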

Results

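Gene expression was measured by RNA-seq in 2 libraries of cells labelled MCF-7, an established breast cancer cell line of the luminal, estrogen receptor-positive type. The edited library came from a clone in which CRISPR/Cas9 had been directed at FASN, the gene of fatty acid synthase, which builds palmitate from acetyl-CoA and malonyl-CoA. The control library came from cells described as negative for the edit. The comparison asks how the transcriptome of the edited clone differs from that of the control. The deposited table lists 28395 genes, with values scaled to the same total in both libraries. The steps in its values gave back 1135391 reads for the control and 332680 for the edited library, a 3.41-fold difference in depth. Reads were found for 14025 genes (49.4% of the table) in the control and for 12060 (42.5%) in the edited library. With 1 library per group, no difference reported here has a replicate check. Intervals and exact binomial tests cover counting error only and compare these 2 libraries, not the conditions.

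FASN was 5.11-fold lower in the edited library (95% interval 3.36 to 8.15). It had 401 reads in the control and 23 in the edited library, which are scaled values of 259 and 50.7. The difference passed the exact binomial test on the reads, with a Benjamini-Hochberg adjusted p of 7.44e-20 over the 14328 genes with reads. The authors' deposited table gives a log2 ratio of -2.35 for FASN. On hg38, FASN (Entrez gene 2194) lies on the minus strand of chromosome 17 from 82078338 to 82098294, and its canonical transcript has 43 exons. The position of the edit within the gene is not given in the sources used here. The list of 26 genes next to FASN on 17q25 was inside its random lists. It had a median log2 ratio of -0.05, at percentile 17.5 of matched random lists, and its median ran from -0.32 with equal upper quartiles to 0.19 with the trend on GC content removed, inside its random lists under each alternative. Among these neighbours MAFG and P4HB were lower and ALYREF was higher past the exact binomial test over all genes, and adjusted over the list alone 2 were higher and 2 lower.

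Genes of cell division were higher in the edited library. Of 25 genes that act in G2 and mitosis, 22 were higher past the exact binomial test over all genes, 23 adjusted over the list alone, and none was lower. MKI67, the gene of the proliferation antigen Ki-67, was 4.04-fold higher (95% interval 3.39 to 4.81). TOP2A, the DNA topoisomerase of dividing cells, was 3.64-fold higher (3.10 to 4.28). The mitotic kinase gene PLK1 was 4.04-fold higher (2.91 to 5.62) and the mitotic kinesin gene KIF20A 4.17-fold higher (2.62 to 6.67). The summed reads of the list were 3.13 times as abundant in the edited library (2.94 to 3.32). Of 25 S phase genes, 12 were higher past the same test, 16 adjusted over the list alone, and none was lower. RRM1, a subunit of ribonucleotide reductase, was 2.92-fold higher (2.20 to 3.88), the replication licensing gene CDC6 3.12-fold (2.0 to 4.84) and the DNA polymerase alpha gene POLA1 2.94-fold (1.91 to 4.5). The median log2 ratio was 1.47 for the G2 and mitosis list and 0.99 for the S phase list. Each lay at percentile 100 of 10000 random lists matched on mean expression.

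**Figure D1:**
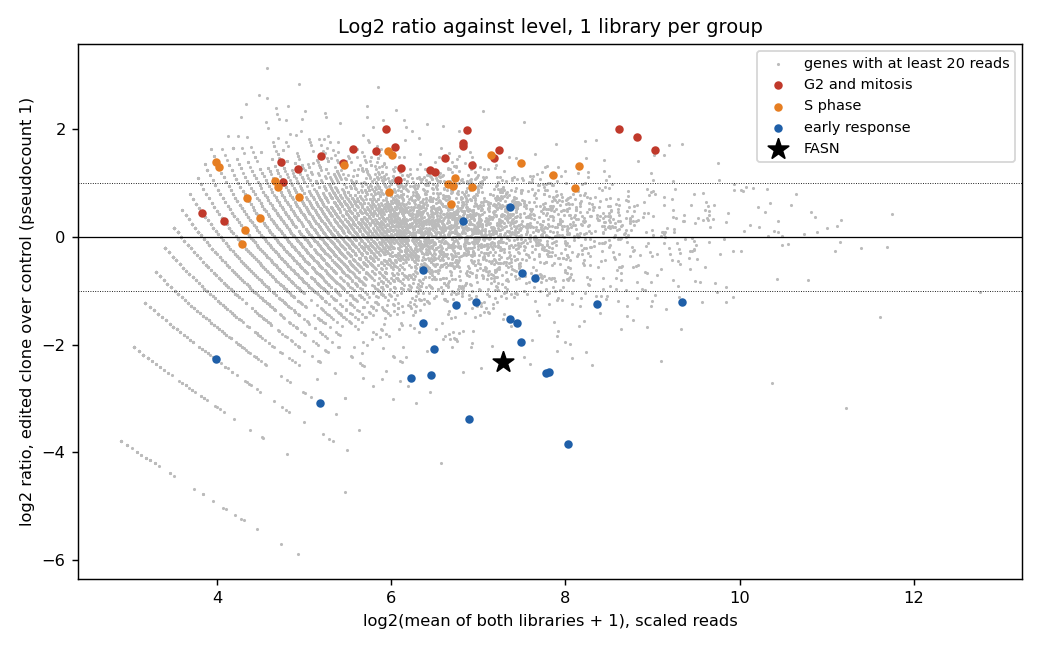
Log2 ratio of the edited clone over the control (pseudocount 1) against log2 of the mean scaled reads of both libraries + 1, for genes with at least 20 reads, 1 library per group. Coloured points are members of the G2 and mitosis, S phase and early response lists, the star is FASN at -2.33, and dotted lines mark 2-fold. The G2 and mitosis points centre on 1.47 and 17 of the 24 early response genes are at least 2-fold lower.

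Early response genes, which growth factors and stress switch on within minutes, were lower in the edited library. Of the 24 on the list, 19 were lower past the exact binomial test over all genes, 20 adjusted over the list alone, and FOSL1 was higher in both counts. EGR1, a zinc finger transcription factor, was 14.8-fold lower (95% interval 8.90 to 26.5). The nuclear receptor gene NR4A1 was 10.9-fold lower (5.66 to 24.0) with 334 reads in the control and 9 in the edited library. FOS was 9.67-fold lower (3.21 to 47.7), with 99 reads in the control and 3 in the edited library. EGR3 was 6.41-fold lower (3.31 to 14.2). The list median was -1.56, below all of its 10000 random lists (percentile 0), and the summed reads of the list in the edited library were 0.362 of those in the control after scaling (0.337 to 0.388).

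Targets of p53 were lower as a group, with a median log2 ratio of -0.52 at percentile 0.240. Of 26 genes, 5 were lower past the exact binomial test over all genes, 7 adjusted over the list alone, and none was higher. CDKN1A, with the most reads on the list (479 and 152), was 1.08-fold higher (0.896 to 1.30). MDM2 was 1.35-fold lower (0.939 to 1.98), and neither of them passed in either count. PPM1D, a phosphatase gene, was 3.49-fold lower (2.26 to 5.66) and the secreted factor gene GDF15 3.41-fold lower (2.23 to 5.48). TP53INP1, with 20 reads against 0, was 1.95-fold lower against the floor of 3 reads. The exact 95% upper limit of its ratio was 0.691, which allows a smaller fold. TP53INP1 passed over the list alone and not over all genes (adjusted p = 0.0878 over all genes by the exact binomial test). In the apoptosis list, BCL2 and MCL1, which protect cells from death, were 2.95-fold (2.30 to 3.85) and 2.67-fold lower (2.13 to 3.39), the pro-death gene BMF was 2.86-fold lower (1.58 to 5.69), and CASP3 was 2.03-fold higher (1.26 to 3.23). These were the 4 of 25 apoptosis genes past the test, both over all genes and adjusted over the list alone, and the list median of -0.14 lay at percentile 17.3 and was 0.00 with the median ratio set to 0.

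NF-kB and cytokine genes had a median of -0.46 at percentile 0.360, but 9 of the 22 had 3 or fewer reads in the control. NFKB2 was 1.88-fold lower (1.19 to 3.09), the cytokine gene LIF 1.68-fold lower (1.24 to 2.31) and IL6 3.41-fold higher (1.71 to 6.81) past the exact binomial test over all genes. Adjusted over the list alone, 3 were lower and 1 higher. The list no longer stood apart when the control was thinned to the depth of the edited library (median 0.00, percentile 11.4) or when the trend on GC content was removed (-0.42, percentile 2.92). It stood apart among genes with at least 20 reads (percentile 1.87).

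Cholesterol synthesis and LDL uptake genes were higher in the edited library. The list of 24 had a median log2 ratio of 0.78 at percentile 100, with 9 genes higher past the exact binomial test, both over all genes and adjusted over the list alone, and none lower. HMGCS1, which makes HMG-CoA for the mevalonate pathway, was 2.40-fold higher (1.49 to 3.82), the squalene epoxidase gene SQLE 2.53-fold (1.34 to 4.68), FDPS 2.31-fold (1.33 to 3.93) and DHCR7, which makes cholesterol in the last step of one branch, 2.31-fold (1.63 to 3.26). Among 19 sterol and lipid regulators, PPARG, a nuclear receptor of fat cell differentiation, was 3.96-fold higher (2.83 to 5.57), and MLX was also higher. SCAP, the sterol-sensing escort protein of the SREBP transcription factors, was 2.34-fold lower (1.52 to 3.79). These were the list's calls both over all genes and adjusted over the list alone, and its median was 0.06 (percentile 66.5), or -0.19 with equal upper quartiles.

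The other genes of fatty acid synthesis and desaturation did not share one direction. Besides FASN, ELOVL5 and FADS3 were lower and SCD and ELOVL1 higher past the exact binomial test, the same counts of 3 and 2 adjusted over the list alone. SCD, the stearoyl-CoA desaturase, was 2.02-fold higher (1.65 to 2.48), ELOVL1 1.98-fold higher (1.39 to 2.78) and FADS3 1.99-fold lower (1.34 to 3.05). The median of the 24 genes was -0.02 (percentile 29.4), and 0.02 when the median ratio of genes was set to 0. Of 24 genes of fatty acid uptake and binding, 4 were higher and 1 lower in both counts, among them ACSL5, which activates fatty acids, 2.51-fold higher (1.81 to 3.45), and LRP8 2.23-fold higher (1.66 to 2.98). Its median was 0.00 with 10 genes at 3 or fewer control reads. In fatty acid oxidation 1 of 27 genes passed over all genes, EHHADH, 2.39-fold lower (1.31 to 4.79), and none adjusted over the list alone (median 0.14, percentile 93.3, 0.00 with equal upper quartiles). Over genes with at least 20 reads that median was 0.41 and stood apart (percentile 98.8). ABHD5, a cofactor of fat breakdown, was 3.04-fold lower (1.47 to 7.27), the 1 call among 29 genes of glycerolipids and lipid droplets in both counts (median 0.00, -0.07 with equal upper quartiles). Of 34 phospholipid and sphingolipid genes, 1 was higher and 3 lower in both counts, ETNK1 by 3.49-fold (1.89 to 7.16) and LPCAT4 by 2.70-fold (1.40 to 5.81). Their median was -0.04 (percentile 21.99), and 0.07 with the median ratio set to 0. None of 10 genes of mitochondrial fatty acid synthesis passed over all genes or adjusted over the list alone (median 0.09, percentile 85.9, -0.04 with equal upper quartiles).

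**Figure D2:**
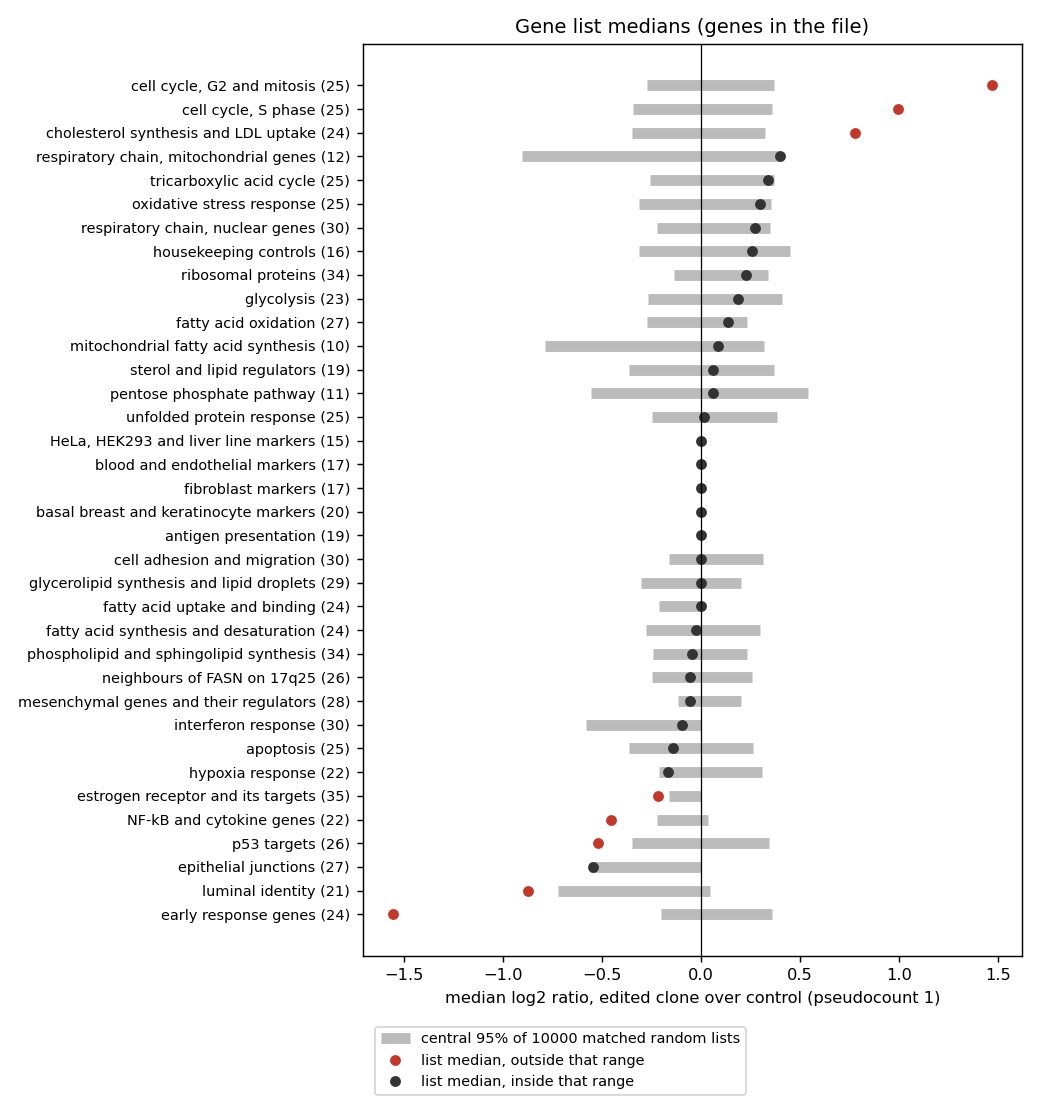
Median log2 ratio of the edited clone over the control (pseudocount 1) for each of 36 gene lists, with the number of genes in the file in brackets. Grey bars span the central 95% of 10000 random lists matched on mean expression, and the 8 red points lie outside their bar, from -1.56 for early response genes to 1.47 for G2 and mitosis.

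Marker genes of luminal breast cells were unevenly covered, and several had few or no reads in both libraries. ESR1, the estrogen receptor gene, had 2 reads in the control and 0 in the edited library, GATA3 had 0 and 1, FOXA1 2 and 0, and CDH1, the gene of E-cadherin, 0 and 0. Other luminal genes were well covered, with 192 and 31 reads for the keratin gene KRT8, 167 and 38 for KRT18, 239 and 38 for the receptor gene ERBB2 and 228 and 35 for XBP1. These 8 were chosen after their values were seen. Of the 21 genes on the luminal identity list, 10 had 3 or fewer reads in the control. No fold is given for such genes, since both libraries are at or under the floor of 3 reads. Of the others, 7 were lower past the exact binomial test, both over all genes and adjusted over the list alone, and none was higher. The surface marker gene CD24 was 16.8-fold lower (4.56 to 141), the epithelial transcription factor gene ELF3 9.0-fold (4.29 to 22.7), EPCAM 8.40-fold (2.78 to 41.5) and TFAP2A 3.42-fold (1.49 to 9.63). The folds of CD24 and EPCAM rest on 2 and 3 edited reads, against 115 and 86 in the control. The list median was -0.87 at percentile 0.0300, and -1.31 over genes with at least 20 reads. In thinned controls it stayed below its random lists' central 95% in 86 of 100 draws.

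Estrogen receptor targets had a median of -0.22 (percentile 1.10), with 15 of 35 genes at 3 or fewer control reads. CCND1, the gene of cyclin D1, was 2.88-fold higher (2.503 to 3.31), SLC7A5 was also higher, and 9 genes were lower, both over all genes and adjusted over the list alone. The lower genes included EGR3, FOS and BCL2, which other lists hold too. Without the members of other lists the median was 0.00, as it was with a thinned control. Over genes with at least 20 reads it was -0.92 (percentile 0), and -0.75 and -0.85 with the trends on GC content and length removed. In the list of 27 epithelial junction genes, EPCAM and F11R were lower and CLDN4, a claudin, was 1.77-fold higher (1.36 to 2.29) over all genes, and adjusted over the list alone 3 were lower and 1 higher. F11R, a junctional adhesion molecule gene, was 4.59-fold lower (1.48 to 23.1), with 47 reads in the control and 3 in the edited library. The median of -0.54 lay at percentile 2.60, just inside the range of random lists, with 11 genes at 3 or fewer control reads. It stood apart with equal upper quartiles (-0.81, percentile 0.0600), a pseudocount of 5, matching in 5 bins or the GC trend removed. With a thinned control it stood apart by the median percentile over draws (1.55), but in only 58 of 100 draws.

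Several mesenchymal genes were abundant in both libraries, and the list went both ways, with 6 of its 28 genes at 3 or fewer control reads. FN1, the gene of fibronectin, had 14338 reads in the control, the highest count of any gene there, and 2061 in the edited library. These were 1.26% and 0.620% of the reads of each library. VIM, the gene of vimentin, was 1.87-fold higher (1.71 to 2.04) with 1373 and 751 reads, and the hyaluronan receptor gene CD44 2.08-fold higher (1.80 to 2.39). CCN1, a secreted matrix protein gene, was 4.97-fold lower (3.98 to 6.28) and TGFB2 2.44-fold lower (1.70 to 3.62). LOXL2 had 26 reads against 0 and was 2.54-fold lower against the floor of 3 reads. Over the list, 5 genes were higher and 6 lower over all genes, 5 and 7 adjusted over the list alone, with a median of -0.05 (percentile 6.11) that was 0.00 with the median ratio set to 0. Of 30 adhesion and migration genes, 5 were higher and 5 lower over all genes, 5 and 9 adjusted over the list alone. PXN, the gene of paxillin, was 2.90-fold higher (2.502 to 3.35), and the integrin gene ITGB4 and the adhesion gene L1CAM were 6.67-fold (3.31 to 15.7) and 4.40-fold lower (1.80 to 13.9). Their median was 0.00 (percentile 26.8), and -0.23 with equal upper quartiles.

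Markers of blood and endothelial cells, and of HeLa, HEK293 and liver lines, mostly had few or no reads. The basal and fibroblast lists were mixed. In the control, ITGB4 had 182 reads and EGFR 126 on the basal list, and COL6A2 had 508 and SPARC 378 on the fibroblast list. Of 20 basal breast and keratinocyte markers, 13 had 3 or fewer reads in the control, as did 9 of 17 fibroblast markers, 15 of 17 blood and endothelial markers and 14 of 15 markers of HeLa, HEK293 and liver lines. Each of the 4 lists had a median of 0.00, set by members without reads. Over genes with at least 20 reads the basal list had a median of -0.92 (percentile 0.555) and the fibroblast list -0.63 (percentile 1.39), the latter -0.25 and inside the range with the GC trend removed. In the basal list VIM was higher and ITGB4 and FOXC1 lower over all genes, and adjusted over the list alone 1 was higher and 3 lower. In the fibroblast list VIM was higher and 3 genes were lower, 4 adjusted over the list alone, among them the collagen gene COL5A1 by 1.93-fold (1.25 to 3.10) and SPARC by 2.01-fold (1.51 to 2.72). No blood, endothelial, HeLa, HEK293 or liver line marker passed over all genes or adjusted over the list alone.

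**Figure D3:**
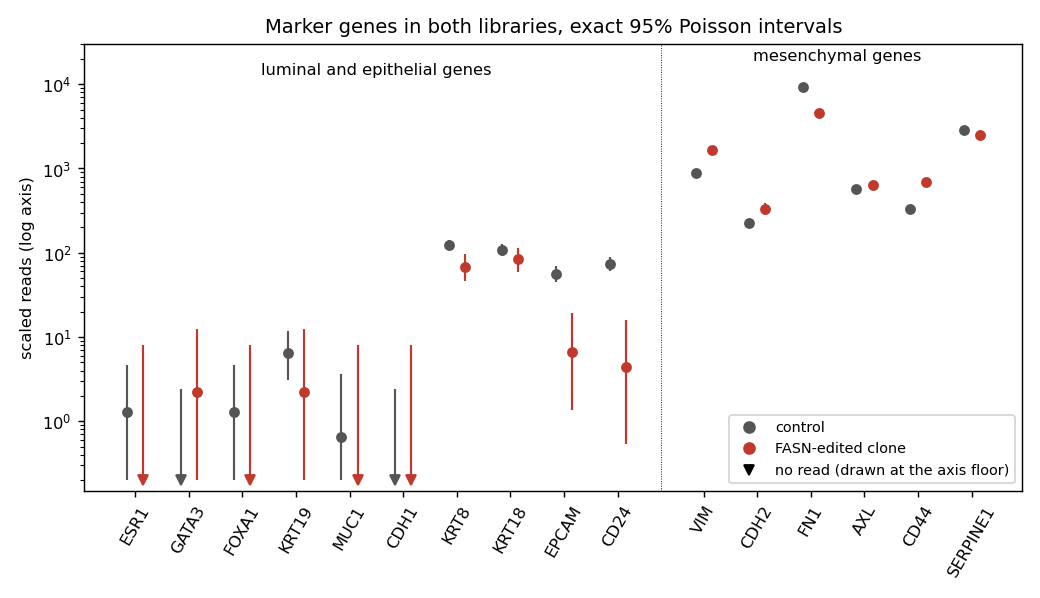
Scaled reads (log axis) of 10 luminal or epithelial and 6 mesenchymal genes, chosen after their values were seen, in the control (grey) and the edited clone (red), with exact 95% Poisson intervals that cover counting error only. Triangles on the axis floor mark genes without a read, and VIM stands at 888 scaled reads in the control where ESR1 stands at 1.29.

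Genes of energy metabolism gave list medians within the range of random lists as planned, and 2 of these lists left it under alternatives. Of 25 citric acid cycle genes, 5 were higher over all genes and 9 adjusted over the list alone, with none lower. FH, the gene of fumarase, was 2.84-fold higher (1.87 to 4.30) and the citrate synthase gene CS 2.18-fold (1.62 to 2.92), and the list median was 0.34 (percentile 96.1), or 0.07 with equal upper quartiles. Among 30 nuclear genes of the respiratory chain, 3 were higher in both counts, including COX5A at 2.23-fold (1.49 to 3.29), with a median of 0.28 (percentile 92.0), or 0.01 with equal upper quartiles. Genes of the mitochondrial genome, which every cell uses, had few reads, 304 in the control and 115 in the edited library. The 12 mitochondrial genes of the chain, with 165 and 94 reads in all and 4 members at 20 reads or more over both libraries, had a median of 0.40 at the upper edge of the central 95% of random lists and 1 call in both counts, ND1, 4.69-fold higher (2.91 to 7.65). This median stood apart with a pseudocount of 0.1, equal upper quartiles, the median ratio set to 0, matching in 5 bins (percentile 99.1) or genes without reads at their bound (0.08, percentile 98.2). Of 23 glycolysis genes, 7 were higher and 1 lower in both counts. LDHB, the lactate dehydrogenase B gene, was 2.19-fold higher (1.78 to 2.70), the glucose transporter gene SLC2A1 1.72-fold higher (1.36 to 2.17) and PFKFB3 2.13-fold lower (1.73 to 2.64). Their median of 0.19 (percentile 72.0) became -0.08 with equal upper quartiles, and 0.47 over genes with at least 20 reads (percentile 99.2), where it stood apart, as it did with the GC trend (0.49) or the length trend (0.44) removed. In the pentose phosphate list of 11, TALDO1 and DERA were higher and TKT lower in both counts, with a median of 0.06 (percentile 53.7) and -0.20 with equal upper quartiles.

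Among stress lists, 7 of 25 oxidative stress genes were higher and 1 lower over all genes, 9 and 1 adjusted over the list alone. The aldo-keto reductase gene AKR1B10 was 2.80-fold higher (2.17 to 3.61) and the peroxiredoxin gene PRDX1 2.27-fold (1.97 to 2.63), and the median of 0.30 was inside its random lists (percentile 94.1). It was 0.03 with equal upper quartiles, 0.31 with the length trend removed (percentile 84.1), and 0.50 and apart with the GC trend removed (percentile 99.4). The unfolded protein response list split into 5 higher and 5 lower genes of 25 in both counts, with ATF3 2.38-fold lower (1.90 to 3.0), DDIT3 2.29-fold lower (1.47 to 3.75) and CRELD2 2.08-fold higher (1.25 to 3.39). Its median was 0.01 (percentile 30.3), and -0.26 with equal upper quartiles. Of 22 hypoxia genes, VEGFA, SLC2A1 and LOX were higher and BHLHE40 lower in both counts (median -0.17, percentile 4.25). The interferon list of 30 had 1 call in both counts, IRF1, 3.32-fold lower (2.07 to 5.62), with 15 genes at 3 or fewer control reads (median -0.10, percentile 35.6). No antigen presentation gene of 19 passed in either count, B2M had 62 and 17 reads and HLA-B 25 and 2, 10 of the genes were listed at 0 in both libraries, and the median was 0.00.

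Control genes were not level between the libraries. Of 34 ribosomal protein genes, 11 were higher and 3 lower over all genes, 13 and 3 adjusted over the list alone, with RPLP0 at 2.19-fold higher (1.85 to 2.60) and a list median of 0.23 (percentile 86.7). Of 16 housekeeping controls, 6 were higher and 1 lower, 7 and 1 adjusted over the list alone, with TUBA1B at 2.05-fold higher (1.80 to 2.34) and a median of 0.26 (percentile 81.0). Both medians turned with equal upper quartiles, to -0.03 and -0.01. Setting the upper quartiles equal moved the median of genes with at least 20 reads by -0.26 on the log2 scale, and setting the median ratio to 0 moved it by 0.15.

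Over all genes, 1337 were at least 2-fold higher and 2711 at least 2-fold lower in the edited library on the log2(value + 1) scale, which understates changes of low genes. Of these, 562 of the higher and 1111 of the lower genes rested on fewer than 10 reads. In simulated pairs of libraries drawn from the same profile at these depths, a median of 670.5 genes passed the rule as higher and 1335.5 as lower. Higher genes made up 33.0% of the count, against 43.4% with the median ratio set to 0 and 20.7% with equal upper quartiles. Among the 3760 genes with a mean of at least 50 scaled reads, 256 were higher and 273 lower, where the simulation gave medians of 1 and 1.5. The simulated pairs hold counting error only. They do not show how far libraries from separate cultures of the same cells would differ. The exact binomial test with Benjamini-Hochberg adjustment called 865 genes higher and 782 lower. On simulated reads it called 48 of 50 genes raised 4-fold and 16 of 50 lowered to 0.25. It thus misses more lower genes, and counts of higher and lower genes cannot be compared directly.

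By the rule for named genes, the lowest ratio belonged to SFRP4, a secreted Wnt modulator. It had 91 reads in the control and 0 in the edited library, 8.89-fold lower against the floor of 3 reads. The exact 95% upper limit of its ratio was 0.141, which allows a smaller fold. SMPD3, BMP3, GRB7, LRIG1, CACNA2D1, TSPAN7, PRDM1, DACH1, MN1 and CACNA1H also had no read in the edited library. Against the floor they were lower by 7.72-fold for SMPD3 to 4.0-fold for MN1 and CACNA1H. The exact 95% upper limits of their ratios ran from 0.163 for SMPD3 to 0.321 for MN1 and CACNA1H. NTN4, the gene of netrin 4, had 131 reads against 1 and was 38.4-fold lower (6.77 to 1528). That fold is not taken against the floor and cannot be ranked with those that are. All 12 passed the exact binomial test. At the other end, ADAM12, a metalloprotease gene, had 0 reads in the control and 8 in the edited library, 9.10-fold higher against the floor. ADGRL4, ERN2 and C3AR1 had 5 reads against 0, 5.69-fold higher against the floor. ARHGAP30 and the transcribed pseudogene UBE2NL had 4 against 0, 4.55-fold higher against it. These folds take the few edited reads as exact and are not lower limits. The cell division gene CDCA3 was 10.8-fold higher (4.15 to 33.1) and NRIP3 11.4-fold higher (2.93 to 64.3). ANAPC1P1, a pseudogene of the anaphase-promoting complex gene ANAPC1 whose reads are hard to tell from its parent's, had 6 reads against 1. MTOR-AS1, MEG9 and LGR6 had 3 reads against 0, which did not pass (adjusted p = 0.146 by the exact binomial test). MTOR-AS1 lies antisense to MTOR, and whether the counting used strand is not given in the sources used here.

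The authors' deposited table marks 58 genes, 16 higher and 42 lower, which are those with a mean of at least 50 and at least a 4-fold difference. FASN is among the lower genes. All 58 passed the exact binomial test on the reads. The lowest of them was BCAM, a laminin-binding adhesion molecule gene, at 277 reads against 4 and 20.3-fold lower (7.84 to 75). VCAN, the gene of the matrix proteoglycan versican, was 9.10-fold lower (7.94 to 10.5) with 6645 and 214 reads, and the cadherin gene CDH6 6.62-fold lower (5.64 to 7.82). Among the higher genes were KIF2C, a mitotic kinesin, at 4.23-fold (2.76 to 6.50) and FANCD2, a DNA repair gene, at 4.01-fold (2.65 to 6.07). These 5 were chosen after their values were seen.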

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

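Tests chosen only after the data were seen are the binomial test, the limits of a mean of 50 and of 20 reads, the GC, length and thinning checks, and the bound for genes without reads. With 1 library per group, no replicate could be left out. No paired analysis was possible because each group has 1 library and no result comes from a replicated test. Of 497 alternative values, 459 kept their side of the threshold or, for counts, stayed within 1.5 times. None of the 8 lists apart changed direction, but of the 28 lists inside their random lists, 10 had a median that changed sign under at least 1 alternative, in 16 values, 7 of them with equal upper quartiles. In 21 values a list that was inside came to stand apart. These were the mitochondrial respiratory chain, epithelial junction, fatty acid oxidation, glycolysis, oxidative stress, basal and fibroblast lists. FASN stayed lower, from -2.60 to -2.18 on the log2 scale over 5 alternatives. The number of lists apart ran from 6 to 12, against 8, the 6 coming from the setting at the bound discussed below. The 2-fold counts were 577 higher and 1194 lower with a pseudocount of 5, 2891 and 4994 at 1.5-fold, 127 and 711 at 4-fold, 256 and 273 with a mean of at least 50, and 865 and 782 by the exact binomial test. The filter at the 25th percentile was void, since that percentile is 0. Its values could not change, and all are counted among the 459, so that share overstates stability. The blood and endothelial list and the HeLa, HEK293 and liver list, held at 0 by members without reads, stayed at percentile 50 wherever they were run. They are counted there too. The estrogen receptor list lost its call without members of other lists (median 0.00), with genes without reads at their bound (0.00) and with the thinned control (0.00). The NF-kB list lost it less the trend on GC (-0.42), at the bound (0.00) and thinned (-9.7e-05). The luminal list lost it at the bound (0.00). The losses at the bound are built into that setting, which puts at 0 the 10 of 21 luminal, 15 of 35 estrogen receptor and 9 of 22 NF-kB genes at or under the floor in both libraries, and whose random lists for these span 0 to 0, so they say nothing about stability. For the losses without members of other lists and with the trend on GC removed, the cause was not tested. With the control thinned, the estrogen receptor list stood apart and lower in 10 of 100 draws and the NF-kB list in 13. The lower depth of the edited library thus remains open as a cause of both calls. Among genes with at least 20 reads both lists stood apart, so thinning alone does not settle it. The G2 and mitosis, S phase, cholesterol, early response and p53 lists stayed outside their random lists under every alternative run. The depth of the edited library limits what could be seen, since a gene needs more than 3 reads there, or 6.62 scaled units, to pass the floor.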

Other observations

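The test of whether the libraries hold other cells than the label names was chosen only after the results were seen. The 3 lists below were written after single members had been seen, which were left out of them. These 3 lists were not put through the alternatives above. The lower depth of the edited library and the trends on GC content and length were thus not checked for them. Reads in this section are given before scaling, and the control library has 3.41-fold more reads in all. Lysosomal genes were lower in the edited library as a group. The median log2 ratio of 30 genes was -0.57, at percentile 0.01 of matched random lists, and 22 of them lay below 0. The progranulin gene GRN had 947 reads in the control and 84 in the edited library (ratio 0.303, 95% interval 0.239 to 0.379), the acid alpha-glucosidase gene GAA 241 and 25, and the beta-galactosidase gene GLB1 213 and 31. Lysosomal genes may thus be lower together, as a hypothesis from genes seen in the same libraries. Targets of YAP, a coactivator that answers to cell shape and density, and of its TEAD transcription factor partners were lower too. Their 19 genes had a median of -0.87 at percentile 0.01, with 12 below 0, among them AMOTL2 with 837 and 107 reads, CRIM1 with 985 and 146 and AJUBA with 338 and 45. The other 7 lay above 0, namely F3, the tissue factor gene, with 225 and 230 reads, MYOF with 389 and 214, PTPN14, FJX1, ASAP1, AMOTL1 and NT5E.

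Fanconi and homologous recombination genes were higher as a group. The median of 26 genes was 0.66 at percentile 100, and 21 lay above 0. EXO1 had 38 reads in the control and 34 in the edited library (ratio 3.05), BRCA1 126 and 67 (1.81) and FANCI 59 and 36 (2.08), while RAD51 had 18 and 2. Many of these genes are known to be made in S phase, and whether they differ apart from the cell cycle lists was not tested.

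The higher level of cell cycle genes in the edited library was set against technical explanations. With the control thinned to the depth of the edited library, both lists stayed above the central 95% of random lists in 100 of 100 draws (median 1.53 for G2 and mitosis and 1.05 for S phase), which argues against the lower depth of the edited library. With the trend on GC content or transcript length removed, both stayed at percentile 100 (1.45 and 1.03 for GC), which argues against such a bias as the whole cause. The difference may be biological, tied to the edit or to the clone, or may come from how dense or how fast the cells grew when they were taken. The edit, the clone and the culture differ together in 1 library per group, so those remain open and untested.

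The lower level of early response genes was weighed in the same way. The list stayed below the central 95% in 100 of 100 thinned draws (median -1.53), which argues against the lower depth of the edited library. It stayed at percentile 0 after the trend on GC content (-1.67) or transcript length (-1.53) was removed, which argues against such a bias as the whole cause. EGR1, FOS and their relatives respond within minutes to fresh serum, handling and stress, so a difference in handling at harvest could give the same pattern as the edit. No value in these tables separates handling from the edit or the clone.

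The few reads on luminal genes, in libraries labelled MCF-7, were weighed against loss of reads over whole regions and against cells or files other than the label names. Of the 10 luminal genes with 3 or fewer control reads, 8 (80%, exact 95% interval 44.4 to 97.48) had at least 3 genes with 20 or more control reads among their 10 nearest, FOXA1 with 2 and TFAP2B with 0 being the exceptions. Loss over whole regions was set to give under 20%, which lies below this interval, so the value argues against it for the set and leaves it open for FOXA1 and TFAP2B. In all, 47.6% of the luminal list had 3 or fewer control reads, against 1.12% of 89 respiratory chain, ribosomal and citric acid cycle genes. This share restates the pattern and decides nothing. The count of neighbours reaches whole regions only and cannot see reads lost on single genes. For the few luminal reads, other cells or files, such lost reads and a loss of luminal expression in these cells cannot be told apart. No biological explanation was tested. Lost reads would not account for abundant mesenchymal genes, such as FN1 with 14338 control reads and VIM with 1373. Of the 28 mesenchymal genes, 6 were at or under the floor in both libraries. Whether that abundance differs from other MCF-7 cultures was not tested.

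In the MHC region of chromosome 6, 154 of 166 protein-coding genes (92.8%) were listed at 0 in both libraries, with starts from 28525881 to 33453083 on hg38, against 6121 of 19005 elsewhere (32.2%). Genes that most cells use, such as TUBB, RPS18 and CSNK2B, are among them, so a 0 there is given only as listed at 0, which covers 9 of the 10 antigen presentation genes at 0. RPS9 on another chromosome is listed at 0 as well. ACACA, the acetyl-CoA carboxylase gene just upstream of FASN in fatty acid synthesis, had 2 reads in the control and 1 in the edited library, while ACLY had 2204 and 651.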
